A study of Mus musculus with 12 samples.

How the data were processed

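Polyadenylated RNA of C57BL/6 mouse ESC-derived cardiac precursors was sequenced from stranded dUTP libraries, with 2 libraries for each of 3 degron lines with and without 50 µM of an auxin analog. The authors deposited 1 table of TPM values (reads scaled for transcript length and library size) with 35856 rows named by gene symbol and 12 library columns. Per the labels, reads were aligned with STAR 2.6.1d to the mouse build mm10, and the program and annotation behind the TPM values are not given in the sources used here. The table held 9632 rows at 0 in every library, 27 names that look like dates, as spreadsheets make from symbols, 2 duplicated names, and no mitochondrial transcripts. Library columns were matched to groups by their names, and no column was left unused.

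The TPM values of a library step in equal units once divided by a length common to all libraries, so whole reads could be recovered: 100% of the values above 0 lay within 0.001 reads of a whole number. The recovered reads of replicates 1 and 2 numbered 17173666 and 16577655 in untreated SUZ12-AID, 10139297 and 10803152 in untreated MTF2-AID, and 13280980 and 12032927 in untreated AID-JARID2. With auxin they were 13906901 and 11008994, 11895529 and 12314719, and 14391497 and 16911757 in the same order of lines. Pearson r of log2(TPM + 1) between replicates was 0.988 to 0.992 across genes, which are not independent replicates. The median absolute log2 difference between replicates was 0.195 in untreated and 0.144 in auxin SUZ12-AID, 0.103 and 0.088 in MTF2-AID, and 0.096 and 0.089 in AID-JARID2. In 49.3%, 45.9% and 72.7% of genes both auxin libraries lay on the same side of both untreated ones in SUZ12-AID, MTF2-AID and AID-JARID2, where chance gives 33.3%.

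Genes with at least 1 TPM in at least 2 libraries were kept, 15663 in all, of which 1976 had placeholder symbols and 420 were short RNAs that such libraries do not measure well. A linear model with 1 term per group was fitted to log2(TPM + 1) of the 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend), with 6 residual and 3.9 prior degrees of freedom. Tests were two-sided, and p values were adjusted over the genes kept by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were auxin against untreated in each line, the average of these effects, their differences between lines, and the untreated lines against each other. The comparisons, tests, gene lists, alternatives and the rule for naming genes were written down before the data were examined, except where said otherwise.

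Of 29 gene lists fixed in this way, 28 had at least 5 members among the genes kept. The list of mitochondrial transcripts had 0 and was not measured. Lists share some members. Each was tested with camera in limma, which compares a list with the other genes, at a preset correlation of 0.01 between genes, and p values were adjusted over all lists and the 3 lines. Camera with an estimated correlation and fry were the alternatives. Beside each count over all genes a count adjusted over the list alone is given. Shared calls were tested by a two-sided Fisher exact test against the product of both counts over the number of genes kept, adjusted over 12 such tests. Each line had its own untreated libraries.

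Genes were named by rule. Suz12, Mtf2 and Jarid2 were named in every group. For each line, the 12 largest increases and 12 largest decreases were taken among genes that passed, had both auxin libraries on the same side of both untreated ones, and had a mean of at least 5 TPM in the higher group. The average gave 10 and 10 genes, each difference between lines and each untreated pair 5 and 5, and each list up to 4 called members per line. Placeholder symbols and pseudogenes were counted and not named, and members that moved against their list, named without values, were added after the values were seen. Some genes that the rule takes are not reported here. Positions come from GENCODE vM21 on mm10, which may differ from the annotation behind the values.

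The test was run once on simulated reads with the depth of these libraries and, for all genes of a group, 1 average replicate spread. In each line 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. The test recovered 82.1%, 94% and 100% in SUZ12-AID, 77.6%, 97% and 98.5% in MTF2-AID, and 71.6%, 91% and 98.5% in AID-JARID2. False calls were 120 of 304 (39.5%) in SUZ12-AID, 32 of 214 (15%) in MTF2-AID and 16 of 190 (8.4%) in AID-JARID2. With a variance weight per line from limma (0.5, 1.29 and 1.54) false calls were 18 of 178 (10.1%), 49 of 234 (20.9%) and 31 of 216 (14.4%), and with the libraries of each line alone 18.2%, 20.4% and 19.7%. A changed list was called in each line and 0 of 27 unchanged lists were. Simulated genes varied independently of each other, so this does not test the preset correlation or false calls among lists of correlated genes. Far fewer genes were changed than were called in the real SUZ12-AID and AID-JARID2 data, so the shares of false calls do not carry over to those calls.

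The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, no trend, the libraries of the compared groups only, the replicate number as a block, a minimum absolute log2 fold change of 1, and each library left out in turn. A further 4 were chosen after seeing the data: voom in limma on the recovered reads (at least 10 reads in 2 libraries), reads thinned to the shallowest library, no short RNAs, and the variance weight per line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.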

Results

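Polyadenylated RNA was sequenced from cardiac precursors (CPs), mesodermal cells on the way to heart muscle, that were grown from C57BL/6 mouse embryonic stem cells (ESCs). The cells came from 3 lines in which a subunit of Polycomb repressive complex 2 (PRC2), a histone methyltransferase that silences developmental genes, carried an auxin-inducible degron (AID). With the plant protein TIR1 in the cell, auxin marks a protein with this tag for degradation. SUZ12 is part of the core of PRC2, and MTF2 and JARID2 are accessory subunits of different forms of the complex. Each of the lines SUZ12-AID, MTF2-AID and AID-JARID2 gave 2 untreated libraries and 2 libraries of cells given 50 µM of an auxin analog, 12 libraries in 6 groups. The protocol had 48 h as embryoid bodies, 43 h after reaggregation and 32 h as a monolayer, and the labels give no start or length of the auxin treatment. The values, in TPM (transcripts scaled to the same total in each library), imply 10139297 to 17173666 assigned reads per library. In each library 18964 to 21026 genes were above 0. Values are given as means ± SD over n = 2 libraries per group. Adjusted p values measure only the spread between these libraries, which the series calls biological replicates without saying whether they were separate cultures.

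**Figure D1:**
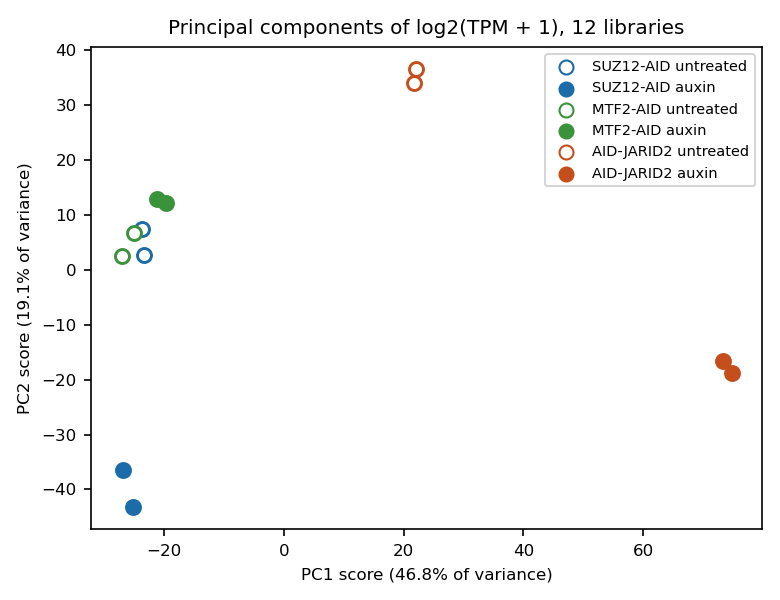
Scores of the 12 libraries on the first principal components of log2(TPM + 1). PC1 on the x axis held 46.8% of the variance and PC2 is on the y axis. Open points are untreated, filled points auxin, and colours give the line. On PC1 the AID-JARID2 auxin libraries lay at 73.4 and 74.7, the untreated AID-JARID2 libraries at 21.7 and 22.1, and the other libraries between -27.1 and -19.7.

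The RNA of the tagged genes was compared first, to see whether auxin changed their transcripts. The degron acts on the protein, so these values do not measure depletion. Suz12 (mm10, chromosome 11, 79993106 to 80034123, plus strand) went from 119.9 ± 9.62 to 108 ± 2.07 TPM in SUZ12-AID and 62.0 ± 1.45 to 60.3 ± 0.480 TPM in MTF2-AID. In AID-JARID2 it rose from 67.3 ± 3.72 to 80.4 ± 4.34 TPM (log2 fold change 0.25, adjusted p = 0.0178). In SUZ12-AID the log2 fold change was -0.15 (adjusted p = 0.179). Its level there was above that of the other lines with and without auxin. Mtf2 (chromosome 5, 108065674 to 108109004, plus strand) went from 24.0 ± 3.79 to 21.8 ± 0.235 TPM in SUZ12-AID, 22.1 ± 0.451 to 25.3 ± 0.910 TPM in MTF2-AID and 30.0 ± 2.23 to 30.4 ± 1.39 TPM in AID-JARID2. No line passed the test for it. Its log2 fold change in MTF2-AID was 0.19 (adjusted p = 0.627). Jarid2 (chromosome 13, 44729474 to 44921643, plus strand) went from 30.1 ± 5.84 to 35.5 ± 3.92 TPM in SUZ12-AID and 34.1 ± 0.884 to 31.6 ± 0.306 TPM in MTF2-AID, neither past the test. In AID-JARID2 the Jarid2 transcript rose from 44.4 ± 1.30 to 109 ± 6.85 TPM (log2 fold change 1.27, SE 0.119, adjusted p = 2.17e-05).

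The auxin comparison within SUZ12-AID asked which transcripts change when the PRC2 core subunit is targeted for degradation. No untagged line was given auxin, and each subunit had a single tagged line. Effects of auxin itself or of the line therefore cannot be told from loss of the subunit, here and in the other lines. Cdkn2a (chromosome 4, 89274471 to 89294653, minus strand), which encodes cell-cycle inhibitors and is a classic Polycomb target, rose from 6.54 ± 1.35 to 84.8 ± 5.35 TPM (log2 fold change 3.52, SE 0.176, adjusted p = 1.32e-05). Its neighbour Cdkn2b (89306299 to 89311039, minus strand) rose from 5.17 ± 0.0869 to 25.6 ± 5.62 TPM. The cardiac transcription factor Nkx2-5 (chromosome 17, 26838664 to 26845009, minus strand) rose from 2.25 ± 0.740 to 25.9 ± 3.57 TPM (log2 fold change 3.06, adjusted p = 3.11e-05). The largest increase under the selection rule was that of Esx1, an X-linked homeobox gene of placenta and testis, from 0.400 ± 0.0756 to 24.1 ± 2.48 TPM (log2 fold change 4.16, adjusted p = 3.09e-05). The T-box gene Tbx15 rose from 0.577 ± 0.0537 to 17.2 ± 0.464 TPM, and the keratin Krt7 from 3.30 ± 1.35 to 34.4 ± 4.11 TPM. The annexin Anxa1 rose from 11.9 ± 0.124 to 82.8 ± 15.9 TPM and the endothelial claudin Cldn5 from 2.00 ± 0.671 to 17.9 ± 4.14 TPM. Gprc5a, Rhox6 and Vax2 rose by 2.93, 2.62 and 2.53 on the log2 scale. Of the genes of the rule that fell, the embryonic globin Hbb-bh1 (chromosome 7, 103841637 to 103843164, minus strand) changed most, from 34.4 ± 9.56 to 0.606 ± 0.334 TPM (log2 fold change -4.45, SE 0.396, adjusted p = 1.22e-04). The globin Hba-x fell from 54 reads in the untreated libraries to a value listed at 0 in both auxin libraries. The caudal homeobox gene Cdx2 fell from 223 ± 15.6 to 86.0 ± 18.1 TPM, Hoxb6 from 16.98 ± 1.52 to 3.69 ± 0.910 TPM and Hoxb1 from 7.97 ± 0.629 to 1.94 ± 0.310 TPM. Pitx1 fell from 30.6 ± 1.10 to 11.7 ± 4.21 TPM and Cldn11 from 27.7 ± 2.67 to 6.53 ± 0.963 TPM. The histone gene Hist1h2ag fell from 8.98 ± 0.646 to 3.07 ± 2.32 TPM, and its call was lost without untreated replicate 1 or auxin replicate 2. The selection rule also took 6 short RNA genes with few reads, AF357359 and Mir6913 among the increases and Mir145a, Mir6945, Scarna2 and Snora78 among the decreases.

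With limma, 2362 of 15663 genes rose and 635 fell in SUZ12-AID at an adjusted p under 0.05, and 664 and 40 of these changed at least 2-fold. The latter numbered 564 and 50 with median-of-ratios scaling and 353 and 95 with quantile normalization. They were 140 and 15 with a pseudocount of 5, which shrinks fold changes by construction, and 933 and 47 with 0.1. Of the 2362 increased genes, 398 had a mean under 1 TPM without auxin. The share of increases among calls was 78.8%, but 61% (2154 higher, 1376 lower) with median-of-ratios scaling and 53.1% (1605 higher, 1418 lower) with quantile normalization. The median log2 fold change of all genes was 0.06, 0.00 and -0.04 in turn. Without untreated replicate 1 the share was 56.1% (1816 higher, 1423 lower). Without auxin replicate 2 the calls dropped to 1061 higher and 261 lower. Data were also simulated with 1 average replicate spread per group and far fewer changed genes than were called here. Such shares of false calls do not carry over to the real calls. In the simulation 120 of 304 SUZ12-AID calls (39.5%) were false, against 18 of 178 (10.1%) with a variance weight per line. On the real data these weights called 979 higher and 215 lower, all 1194 of them among the 2997. As the weights left fewer calls, small changes in this line carry more doubt than the adjusted p states.

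Endothelial genes rose as a list in SUZ12-AID: of 21 members 17 rose and 1 fell, 18 and 1 adjusted over the list alone (median log2 fold change 1.04, camera adjusted p = 1.69e-07, adjusted p = 0.173 with an estimated correlation). The stem cell antigen Cd34 rose from 3.79 ± 1.07 to 20.9 ± 0.758 TPM and the adhesion gene Esam from 3.38 ± 0.549 to 17.3 ± 1.91 TPM. The transcription factor Sox18 (5.75 ± 2.82 to 24.9 ± 3.78 TPM) and the guidance receptor Robo4 (0.953 ± 0.397 to 6.67 ± 0.874 TPM) rose as well, while Pecam1 fell. Of 26 pluripotency genes, 17 rose and 1 fell, 19 and 1 adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 1.1e-06, adjusted p = 0.173 with an estimated correlation). Dppa5a rose from 7.11 ± 0.527 to 34.2 ± 7.23 TPM, Klf5 from 16.1 ± 0.867 to 46.3 ± 8.59 TPM and Sox2 from 3.13 ± 0.716 to 8.78 ± 0.742 TPM, and Lin28a fell. Of 13 surface ectoderm genes 12 rose and 0 fell, 12 and 0 adjusted over the list alone (median log2 fold change 0.92, camera adjusted p = 6.36e-11, adjusted p = 0.13 with an estimated correlation). Cldn4 rose from 183 ± 14.1 to 549 ± 63.0 TPM and Krt19 from 92.9 ± 7.04 to 188 ± 27.5 TPM. Of 15 germline genes, which adult tissues other than the gonads keep silent, 11 rose and 0 fell, 15 and 0 adjusted over the list alone (median log2 fold change 1.08, camera adjusted p = 8.6e-07, adjusted p = 0.14 with an estimated correlation). The transposon regulator Tex19.1 rose from 6.14 ± 1.64 to 18.0 ± 3.69 TPM and the RNA helicase Ddx4 from 1.55 ± 0.150 to 5.53 ± 2.18 TPM. Neural genes rose in 12 of 24 cases and fell in 1, 15 and 1 adjusted over the list alone (median log2 fold change 0.54, camera adjusted p = 4.22e-04, adjusted p = 0.14 with an estimated correlation). Zic1 rose from 0.195 ± 0.0728 to 3.00 ± 0.699 TPM and Irx3 fell from 77.1 ± 0.958 to 31.2 ± 7.45 TPM.

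The list of cell-cycle inhibitors rose with them. Of its 13 members 9 rose and 0 fell, also 9 and 0 adjusted over the list alone (median log2 fold change 0.83, camera adjusted p = 1.04e-06, adjusted p = 0.0693 with an estimated correlation). Beside Cdkn2a and Cdkn2b, Gadd45b rose from 4.48 ± 1.66 to 19.8 ± 2.62 TPM and Btg2 from 65.6 ± 0.203 to 133 ± 23.6 TPM. Among the 9 was Ccnd2, whose product cyclin D2 promotes division rather than stopping it. Of 22 proliferation genes 0 rose and 14 fell, 0 and 18 adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 1.43e-14, adjusted p = 0.102 with an estimated correlation). The topoisomerase Top2a fell from 433 ± 59.7 to 340.0 ± 5.81 TPM and the replication helicase subunit Mcm5 from 305 ± 16.9 to 243 ± 3.39 TPM. Of 19 p53 targets and apoptosis genes 15 rose and 0 fell, 16 and 1 adjusted over the list alone (median log2 fold change 0.74, camera adjusted p = 7.47e-09, adjusted p = 0.13 with an estimated correlation). Perp rose from 60.7 ± 2.20 to 169 ± 21.8 TPM and Fas from 1.28 ± 0.136 to 4.74 ± 1.68 TPM. Of 20 stress genes 11 rose and 3 fell, 11 and 3 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.0244, adjusted p = 0.191 with an estimated correlation). The chaperone Hspb1 rose from 67.0 ± 12.1 to 238 ± 19.2 TPM, while Hspa8, Egr1 and Ier2 fell. Of 7 aryl hydrocarbon receptor targets 4 rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.00608, adjusted p = 0.173 with an estimated correlation). The oxidase Cyp1a1 rose from 3.15 ± 0.623 to 12.8 ± 0.252 TPM and Nqo1 from 8.45 ± 0.105 to 27.1 ± 5.39 TPM. This receptor list passed in 0 of 24 alternatives in MTF2-AID (medians 0.03 to 0.19) and in 0 of 24 in AID-JARID2 (medians 0.19 to 0.89).

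The cardiac progenitor list also rose in SUZ12-AID: of 24 factors 10 rose and 2 fell, 12 and 2 adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.0456, adjusted p = 0.476 with an estimated correlation). Hand2 rose from 48.2 ± 0.0490 to 159.9 ± 12.1 TPM and Hopx from 2.25 ± 0.150 to 10.2 ± 0.313 TPM. Hand1 fell from 2421 ± 185 to 1033 ± 61.4 TPM, and Bmp4 fell too. Of 17 smooth muscle, fibroblast and epicardium genes 2 rose and 2 fell, 4 and 5 adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 0.0483, adjusted p = 0.444 with an estimated correlation). The receptor Pdgfrb fell from 83.3 ± 13.6 to 45.02 ± 1.13 TPM, while Thy1 and Wt1 rose. The cardiac progenitor list passed in 20 of 25 alternatives. It missed the test without untreated replicate 1 (camera adjusted p = 0.0877), auxin replicate 1 (0.161), untreated MTF2-AID replicate 1 (0.0534) or MTF2-AID auxin replicate 2 (0.05). The smooth muscle list passed in 12 of 25, and missed without untreated replicate 1 (0.114) or 2 (0.0878), auxin replicate 2 (0.335) or MTF2-AID auxin replicate 2 (0.0877). The stress list missed without untreated replicate 2 (0.138).

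Lists of SUZ12-AID that missed the test were the Hox genes (3 rose and 5 fell of 24, camera adjusted p = 0.0541), other homeobox genes (14 and 7 of 44, 0.0758), trophoblast (8 and 3 of 12, 0.0795) and endoderm (8 and 1 of 15, 0.0537). So did contractile genes (5 and 0 of 22, 0.158), PRC2 subunits (6 and 2 of 15, 0.288), housekeeping genes (3 and 1 of 20, 0.28) and blood genes. Secreted factors (12 and 4 of 33, 0.0639), neural crest (5 and 1 of 14, 0.106), imprinted genes (9 and 2 of 27, 0.365) and PRC1 subunits (3 and 0 of 20, 0.709) missed it as well. The last ones were the primitive streak (8 and 3 of 21, 0.774), paraxial (4 and 1 of 13, 0.28), intermediate and lateral mesoderm (5 and 4 of 14, 0.962) and histone lists (1 and 1 of 20, 0.323). Of 17 blood genes 2 rose and 7 fell (camera adjusted p = 0.0639), and the median of 0.01 differed in sign from the mean of -0.53. The Hox list passed in 11 of 25 alternatives, endoderm in 10, blood in 7 and trophoblast in 5. Members of other kinds that changed were the PRC1 subunit Bmi1, up from 6.65 ± 0.197 to 21.1 ± 0.678 TPM, and the homeobox gene Six2, up from 6.30 ± 0.209 to 30.0 ± 1.04 TPM. The mesodermal forkhead gene Foxf1 fell from 103 ± 21.1 to 53.9 ± 0.213 TPM.

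The comparison within AID-JARID2 asked the same of JARID2. Genes of early pluripotent cells were among the largest increases under the selection rule. Utf1 (chromosome 7, 139943789 to 139945112, plus strand) went from 30.7 ± 1.37 to 819.8 ± 4.78 TPM (log2 fold change 4.69, SE 0.102, adjusted p = 2.19e-09). Sox2 rose from 5.07 ± 0.876 to 98.8 ± 0.907 TPM (log2 fold change 4.05) and the forkhead gene Foxd3 from 0.805 ± 0.238 to 45.6 ± 1.86 TPM (log2 fold change 4.70). Fgf5, a growth factor of the epiblast, rose from 4.00 ± 0.655 to 85.5 ± 3.30 TPM. The RAS-like gene Eras rose from 2.64 ± 0.0540 to 61.3 ± 3.95 TPM, and the kinase Pim2 from 77.2 ± 11.8 to 1223 ± 8.27 TPM. The receptor Epha2 rose from 11.4 ± 0.843 to 129 ± 7.23 TPM and the phosphodiesterase Pde2a from 1.06 ± 0.420 to 31.5 ± 2.07 TPM. Platr10, Pipox and Fgfbp1 rose by 3.40, 3.37 and 3.26 on the log2 scale, and the short Mir363 rested on 24 reads. Foxf1 (chromosome 8, 121084386 to 121088144, plus strand) fell from 170.2 ± 5.84 to 6.76 ± 0.478 TPM (log2 fold change -4.46, SE 0.119, adjusted p = 4.38e-09). The neighbouring noncoding RNA Fendrr (121054882 to 121083110, minus strand) fell from 29.4 ± 0.314 to 0.925 ± 0.203 TPM. Hand1 (chromosome 11, 57828705 to 57832818, minus strand), a factor of heart and extraembryonic mesoderm, fell from 1858 ± 36.9 to 98.3 ± 11.7 TPM (log2 fold change -4.23, adjusted p = 6.34e-10). Tbx2 fell from 40.4 ± 1.89 to 1.34 ± 0.143 TPM and the caudal gene Cdx4 from 24.4 ± 2.69 to 0.637 ± 0.359 TPM. The imprinted noncoding RNA H19 (chromosome 7, 142575529 to 142578143, minus strand) fell from 2561 ± 77.7 to 142 ± 24.7 TPM (log2 fold change -4.17, adjusted p = 2.22e-09). Its neighbour Igf2 fell from 693 ± 0.465 to 70.1 ± 5.94 TPM. Pmp22 fell from 317 ± 0.926 to 19.5 ± 0.291 TPM, and Ackr3 from 55.7 ± 3.26 to 2.69 ± 0.0856 TPM. Dlk1 fell from 50.6 ± 4.90 to 2.81 ± 0.112 TPM and the collagen Col1a1 from 52.7 ± 2.29 to 3.07 ± 0.105 TPM. Rubie and the short Mir483 had log2 fold changes of -3.95 and -3.88.

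In AID-JARID2, 3053 of 15663 genes rose and 2657 fell, 890 and 635 of them at least 2-fold. Leaving out auxin replicate 2 reduced the 5710 calls to 3697. In the simulated data 16 of 190 AID-JARID2 calls (8.4%) were false, and 91% of genes changed 2-fold were recovered. False calls there were 14.4% with a variance weight per line and 19.7% with the libraries of this line alone.

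Of 24 cardiac progenitor factors 1 rose and 19 fell in AID-JARID2, 1 and 19 adjusted over the list alone (median log2 fold change -1.60, camera adjusted p = 7.56e-13, adjusted p = 0.102 with an estimated correlation). Bmp4 fell from 331 ± 9.12 to 25.1 ± 2.71 TPM and the T-box gene Tbx3 from 135 ± 0.854 to 13.3 ± 1.59 TPM, and Hopx rose. Contractile genes fell in 12 of 22 cases and rose in 3, 3 higher and 12 lower adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 0.00138, adjusted p = 0.14 with an estimated correlation). Cardiac troponin Tnnt2 fell from 19.6 ± 3.38 to 2.77 ± 0.0626 TPM and the atrial light chain Myl4 from 14.2 ± 0.0438 to 2.50 ± 0.603 TPM, while Myl3, Actn2 and Atp2a2 rose. Of 24 Hox genes 0 rose and 14 fell, 0 and 14 adjusted over the list alone (median log2 fold change -1.20, camera adjusted p = 1.56e-08, adjusted p = 0.0693 with an estimated correlation). Hoxb1 fell from 76.2 ± 1.22 to 9.45 ± 1.32 TPM, Hoxb2 from 75.8 ± 0.153 to 7.44 ± 1.23 TPM and Hoxd9 from 14.2 ± 1.94 to 0.435 ± 0.101 TPM. Of 44 other homeobox and paired-box genes 7 rose and 19 fell, 8 and 20 adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 4.98e-04, adjusted p = 0.13 with an estimated correlation). Cdx2 fell from 121 ± 7.11 to 8.64 ± 0.647 TPM and Msx2 from 207 ± 1.17 to 21.1 ± 3.32 TPM. Of 14 genes of intermediate and lateral mesoderm 2 rose and 6 fell, 2 and 6 adjusted over the list alone (median log2 fold change -0.42, camera adjusted p = 0.00915, adjusted p = 0.173 with an estimated correlation), with Lhx1 and Wt1 rising. Of 17 smooth muscle, fibroblast and epicardium genes 4 rose and 10 fell, 4 and 10 adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 0.0206, adjusted p = 0.39 with an estimated correlation). Fibronectin Fn1 fell from 1577 ± 55.6 to 440.5 ± 16.2 TPM and smooth muscle actin Acta2 from 45.5 ± 4.15 to 11.2 ± 1.19 TPM, while Tagln, Cnn1, Wt1 and Thy1 rose.

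Pluripotency genes moved the other way in AID-JARID2: 18 of 26 rose and 3 fell, 18 and 3 adjusted over the list alone (median log2 fold change 0.88, camera adjusted p = 9.14e-06, adjusted p = 0.199 with an estimated correlation), the decreases being Klf4, Tbx3 and Prdm14. Neural genes rose in 15 of 24 cases and fell in 1, 15 and 2 adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 4.75e-06, adjusted p = 0.117 with an estimated correlation). The POU factor Pou3f1 rose from 20.6 ± 0.921 to 169.9 ± 11.2 TPM and the tubulin Tubb3 from 13.1 ± 1.62 to 77.5 ± 4.78 TPM. Elavl3, for a neuronal RNA-binding protein, rose from 0.672 ± 0.404 to 10.9 ± 0.000701 TPM, while Irx3 fell. Of 19 p53 targets 15 rose and 1 fell, 16 and 1 adjusted over the list alone (median log2 fold change 0.82, camera adjusted p = 1.52e-08, adjusted p = 0.13 with an estimated correlation). Of 20 stress genes 14 rose and 1 fell, 15 and 1 adjusted over the list alone (median log2 fold change 0.52, camera adjusted p = 3.48e-07, adjusted p = 0.0693 with an estimated correlation). Perp rose from 30.0 ± 2.42 to 147 ± 9.92 TPM, Trib3 from 10.4 ± 2.46 to 34.0 ± 0.0740 TPM and the amino acid response gene Chac1 from 3.75 ± 0.248 to 16.8 ± 2.36 TPM, while Sesn1 and Dnajb1 fell. Of 27 imprinted genes 3 rose and 16 fell, 3 and 17 adjusted over the list alone (median log2 fold change -0.70, camera adjusted p = 8.6e-07, adjusted p = 0.148 with an estimated correlation). The noncoding Airn fell from 16.0 ± 0.829 to 1.02 ± 0.161 TPM and the cell-cycle inhibitor Cdkn1c from 95.1 ± 11.2 to 26.3 ± 1.17 TPM, while Magel2, Plagl1 and Nnat rose. Secreted signalling factors fell in 19 of 33 cases and rose in 7, 8 higher and 20 lower adjusted over the list alone (median log2 fold change -0.82, camera adjusted p = 1.20e-04, adjusted p = 0.163 with an estimated correlation). Bmp2 fell from 64.1 ± 1.62 to 7.68 ± 1.01 TPM and Bmp5 from 40.2 ± 2.91 to 3.90 ± 0.133 TPM, while Wnt8a, Wnt9a, Fgf4, Fgf5, Fgf17, Chrd and Sfrp1 rose. Of 12 trophoblast genes 4 rose and 6 fell, 4 and 6 adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 0.0246, adjusted p = 0.148 with an estimated correlation). Plac1 fell from 45.4 ± 1.64 to 3.34 ± 0.269 TPM, while Tfap2c, Gata2, Krt7 and Esx1 rose. The trophoblast list passed in 22 of 25 alternatives and missed the test with a variance weight per line (camera adjusted p = 0.0515). Of 20 replication-dependent histone genes 0 rose and 6 fell, 0 and 5 adjusted over the list alone (median log2 fold change -0.58, camera adjusted p = 0.0261, adjusted p = 0.39 with an estimated correlation), and the list missed the test without untreated replicate 1 (camera adjusted p = 0.25).

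Several lists split in AID-JARID2. Of 21 primitive streak and early mesoderm genes 6 rose and 8 fell, 7 and 8 adjusted over the list alone. The median of 0.11 differed in sign from the mean of -0.10 (camera adjusted p = 0.811). Wnt5a fell from 59.9 ± 3.90 to 13.6 ± 0.812 TPM, while Apln rose from 7.74 ± 0.381 to 51.7 ± 3.47 TPM and Nodal from 20.4 ± 2.89 to 93.8 ± 3.80 TPM. Msgn1, of the paraxial list, fell from 185 ± 0.555 to 58.2 ± 0.0333 TPM. Of 21 endothelial genes 5 rose and 5 fell (camera adjusted p = 0.724). The receptor Kdr fell from 127 ± 0.0162 to 17.1 ± 2.92 TPM and Cd34 rose from 0.656 ± 0.112 to 5.10 ± 0.0343 TPM. Surface ectoderm genes rose in 8 of 13 cases and fell in 3 without passing as a list (camera adjusted p = 0.0537), though they passed in 10 of 25 alternatives. Its cadherin Cdh1 rose from 58.5 ± 5.18 to 405 ± 16.9 TPM, and the claudin Cldn6 of the endoderm list from 53.2 ± 6.48 to 464 ± 7.74 TPM. Of 20 PRC1 subunits 6 rose and 7 fell, with Phc1 up from 110.0 ± 0.0377 to 326 ± 3.21 TPM. Of 15 PRC2 subunits 5 rose and 2 fell, Phf1 down from 20.4 ± 0.940 to 12.4 ± 0.107 TPM.

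The comparison within MTF2-AID asked the same of MTF2, and few genes passed. The integrin Itga2b (chromosome 11, 102453297 to 102470122, minus strand), a marker of early blood cells and platelets, fell from 17.9 ± 0.324 to 8.61 ± 0.795 TPM (log2 fold change -0.98, SE 0.111, adjusted p = 0.0134). The cell-cycle inhibitor Cdkn1a fell from 153 ± 0.310 to 115 ± 5.79 TPM (log2 fold change -0.41, adjusted p = 0.0384). The keratin Krt8 rose from 657 ± 9.47 to 862 ± 3.19 TPM (log2 fold change 0.39, adjusted p = 0.00783). The immunoproteasome gene Psmb8 rose from 17.8 ± 0.0891 to 30.4 ± 0.419 TPM (log2 fold change 0.74, adjusted p = 0.00504). Sprr2a2, of the cornified envelope, rose from 9.54 ± 2.75 to 22.3 ± 0.972 TPM (adjusted p = 0.0384), and Cib2, a calcium-binding protein gene, from 4.00 ± 0.332 to 8.003 ± 0.454 TPM (adjusted p = 0.0339). The small nucleolar RNA Snora47 was listed at 0 in both untreated libraries and had 13 reads with auxin. Mir183 and Mir1945, higher with auxin, and Scarletltr, listed at 0 with auxin, also passed and were named after their values were seen. In all, 7 of 15663 genes rose and 3 fell in MTF2-AID, against 1489 at an unadjusted p under 0.05. Without any effect a share of 0.05 of the genes tested would be expected to reach that unadjusted threshold. For 91.1% of genes the 95% interval of the change lay within 2-fold in either direction, against 81.2% in SUZ12-AID and 75.8% in AID-JARID2. The scale of log2(TPM + 1) shrinks changes of genes with low TPM, which raises these shares. Leaving out 1 library changed the 10 calls to 3 for each MTF2-AID auxin replicate, 6 for each AID-JARID2 auxin replicate, 20 for each SUZ12-AID auxin replicate and 40 for each untreated SUZ12-AID replicate. A variance weight per line gave 164. Which direction had more calls changed with the processing: 55 rose and 109 fell with these weights, 18 and 22 without either untreated SUZ12-AID replicate, and 12 and 18 with a pseudocount of 5. Increases and decreases were 9 and 12 without a filter, 5 and 10 without a trend, and 4 and 10 with voom on recovered reads. Of the 7 genes of the selection rule, Snora47 kept its call under each alternative that tested it and the other 6 lost it under at least 1.

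**Figure D2:**
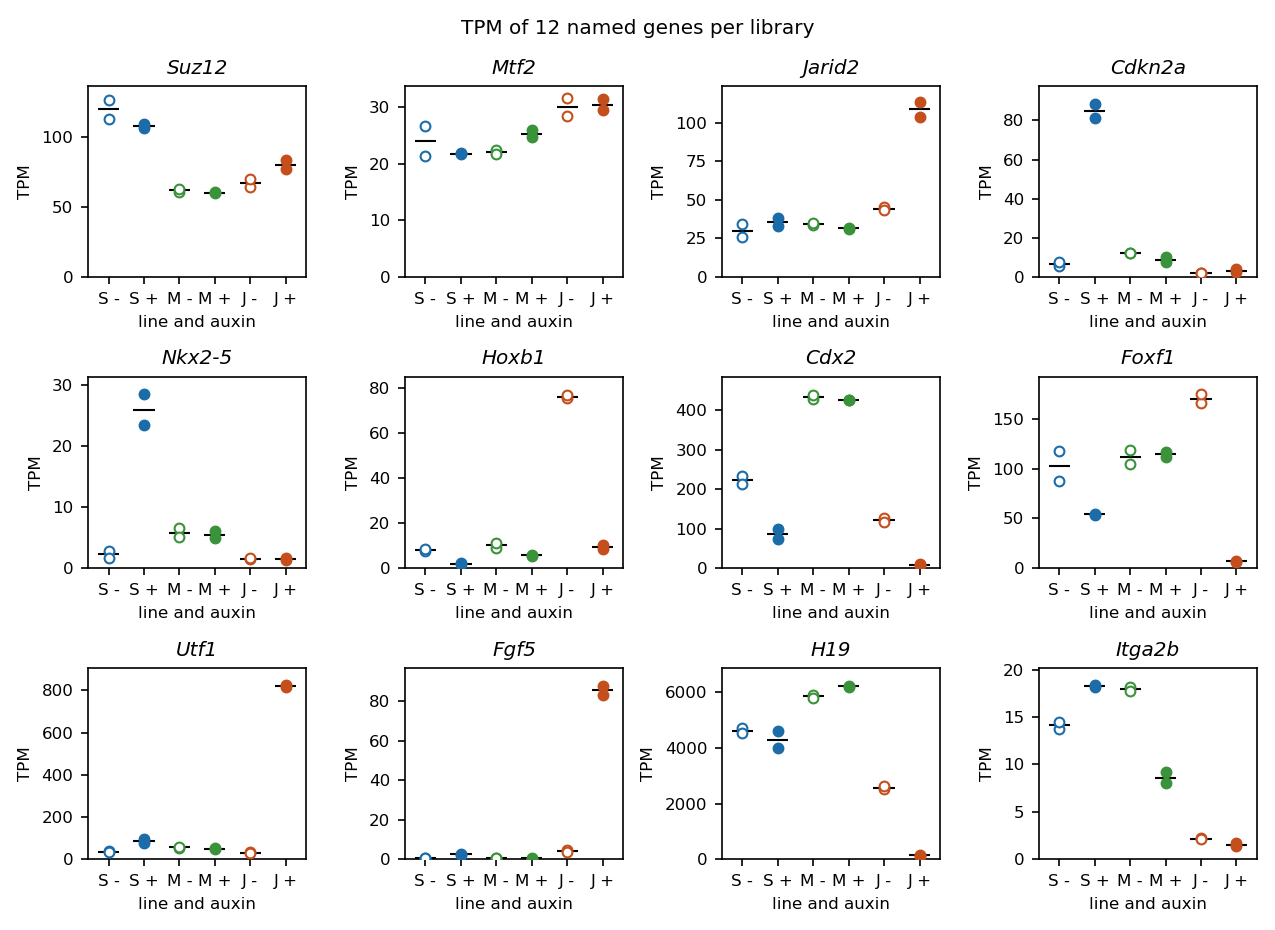
TPM of 12 genes in each library, with S, M and J for SUZ12-AID, MTF2-AID and AID-JARID2, minus for untreated and plus for auxin; points are libraries and lines the means of n = 2. Cdkn2a rose to 84.8 ± 5.35 TPM in SUZ12-AID, Utf1 to 819.8 ± 4.78 TPM in AID-JARID2, and Itga2b fell to 8.61 ± 0.795 TPM in MTF2-AID.

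Endothelial genes were lower as a list in MTF2-AID: of 21 members 0 rose and 0 fell over all genes tested, but 0 and 16 adjusted over the list alone (median log2 fold change -0.70, camera adjusted p = 9.48e-22, adjusted p = 0.0693 with an estimated correlation). Blood genes went the same way, with 0 up and 1 down of 17, 0 and 8 adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 9.99e-10, adjusted p = 0.0693 with an estimated correlation). The p53 targets were lower in small steps, with 0 up and 1 down of 19, 0 and 5 adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 2.65e-10, adjusted p = 0.117 with an estimated correlation). Cell-cycle inhibitors had 0 up and 1 down of 13, 1 and 4 adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 0.0483, adjusted p = 0.173 with an estimated correlation). The 1 decrease in this list and in the p53 list was the same gene, Cdkn1a, and these lists share 2 measured members. Germline genes had 0 and 0 of 15, also 0 and 0 adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 0.00317, adjusted p = 0.289 with an estimated correlation). Lists that were higher had smaller medians. Surface ectoderm had 1 up and 0 down of 13, 5 and 2 adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.00472, adjusted p = 0.39 with an estimated correlation). Trophoblast had 1 and 0 of 12, 4 and 0 adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.00351, adjusted p = 0.117 with an estimated correlation). The 1 increase in the trophoblast and surface ectoderm lists was the same gene, Krt8, and these lists share 3 measured members. Other homeobox genes had 0 and 0 of 44, 7 and 3 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00915, adjusted p = 0.173 with an estimated correlation). Secreted factors had 0 and 0 of 33, 4 and 0 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00477, adjusted p = 0.26 with an estimated correlation). Proliferation genes had 0 and 0 of 22, 0 and 0 adjusted over the list alone (median log2 fold change 0.07, camera adjusted p = 0.0284, adjusted p = 0.476 with an estimated correlation). No member of the Hox (camera adjusted p = 0.854), cardiac progenitor (0.466), pluripotency (0.831) or contractile lists (0.811) passed over all genes tested. The contractile median of 0.05 differed in sign from the mean of -0.02. Cell-cycle inhibitors passed in 11 of 25 alternatives, and missed the test (camera adjusted p = 0.0544 to 0.124) without any 1 of the untreated libraries of the 3 lines or MTF2-AID auxin replicate 2. Without untreated replicate 1 germline and proliferation genes missed it (0.0913 each), as did proliferation genes without auxin replicate 2 (0.122). Other homeobox genes missed it without untreated replicate 2 (0.122) or auxin replicate 2 (0.0811).

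**Figure D3:**
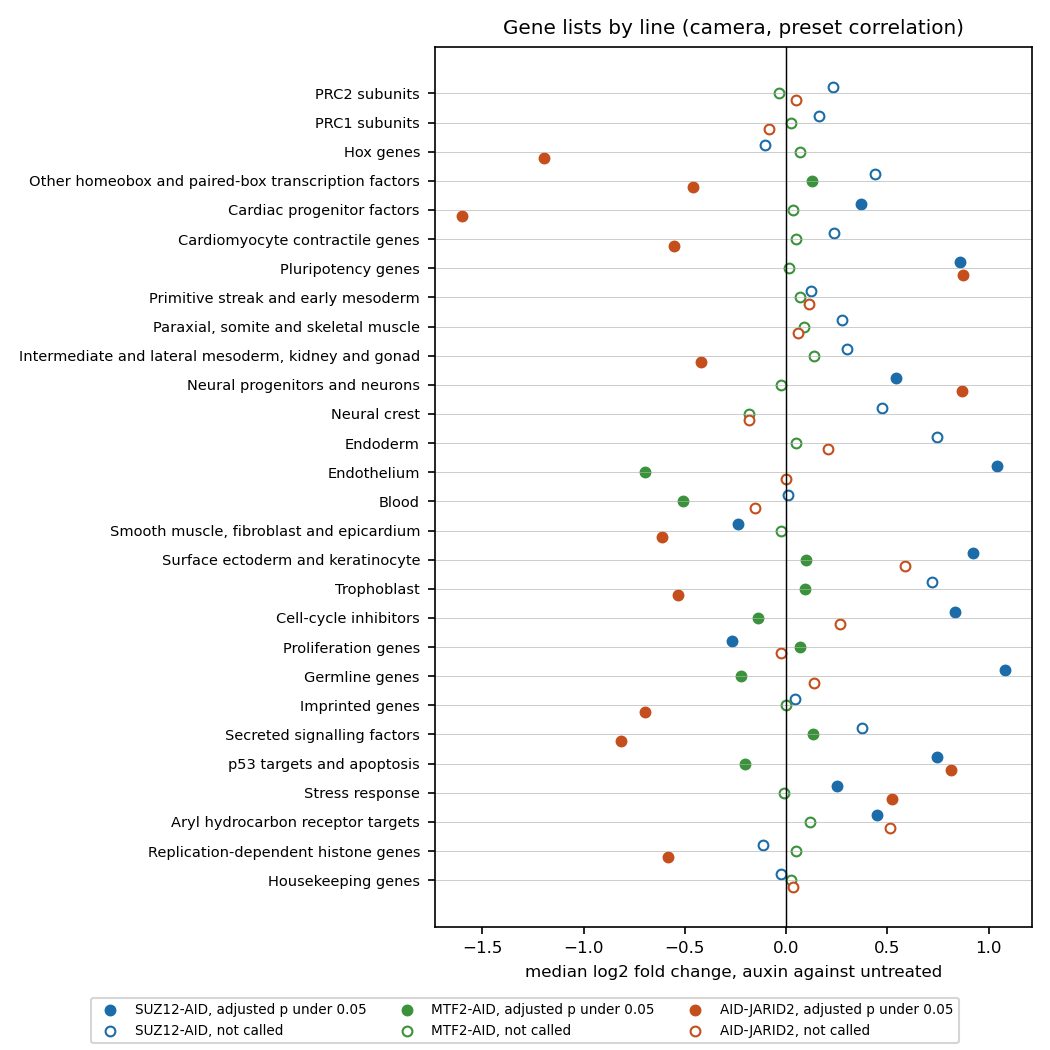
Median log2 fold change with auxin over the measured members of each of 28 gene lists, by line. Filled points passed camera with a preset correlation at an adjusted p under 0.05. The endothelial median was 1.04 in SUZ12-AID, -0.70 in MTF2-AID and 0.00 in AID-JARID2, and the cardiac progenitor median 0.37, 0.03 and -1.60.

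Camera with a preset correlation called 12 of 28 lists in SUZ12-AID, 10 in MTF2-AID and 14 in AID-JARID2. With the correlation estimated per list no call held, and the lowest adjusted p was 0.0693 in each line. The test fry, which asks whether a list's genes move one way without comparing them with other genes, called 24, 6 and 20.

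The average of the 3 auxin effects asked which genes changed in the mean over the lines, which a large effect in 1 line can give. Foxd3 (log2 fold change 2.10), Esx1 (2.10), Spp1 (1.95), Utf1 (1.94), Trh (1.83), Krt7 (1.78), Fgf5 (1.77), Sox2 (1.76), Fgfbp1 (1.65) and Pde2a (1.62) rose most. The matrix protein gene Spp1 went from 3.82 ± 0.676 to 23.5 ± 4.60 TPM in SUZ12-AID and 1.35 ± 0.0649 to 21.5 ± 3.81 TPM in AID-JARID2, and from 2.57 ± 1.06 to 3.31 ± 1.47 TPM in MTF2-AID. Hbb-bh1 (-2.33), Hand1 (-1.81), Foxf1 (-1.78), Hoxb1 (-1.74) and Fendrr (-1.72) fell, with 5 microRNA genes of few reads (Mir145a, Mir32, Mir6999, Mir6945 and Mir7028). Hoxb1 fell from 76.2 ± 1.22 to 9.45 ± 1.32 TPM in AID-JARID2 as in SUZ12-AID, and went from 10.1 ± 1.55 to 5.66 ± 0.377 TPM in MTF2-AID (adjusted p = 0.0957). On average 2655 genes rose and 1509 fell, with 2360 and 2002 under median-of-ratios scaling and 2195 and 2232 under quantile normalization. A gene can pass on average without passing in each line, as Spp1 did (adjusted p = 0.853 in MTF2-AID). The AID-JARID2 effects on Utf1 and Foxf1 differed from those in MTF2-AID by 4.88 and -4.50, so these averages are not effects common to the lines.

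Interaction tests asked where the effect of auxin differed between lines. Cdkn2a and Anxa1 rose in SUZ12-AID and went from 12.3 ± 0.125 to 8.97 ± 1.74 TPM and 6.70 ± 0.483 to 2.98 ± 0.667 TPM in MTF2-AID. The log2 differences between these effects were -3.95 (adjusted p = 1.83e-04) and -3.65 (adjusted p = 7.70e-04). Sox18 rose in SUZ12-AID and went from 13.7 ± 1.34 to 4.37 ± 0.509 TPM in MTF2-AID (difference -3.45, adjusted p = 7.70e-04). Hand2 rose in SUZ12-AID and fell from 47.5 ± 5.76 to 4.18 ± 0.495 TPM in AID-JARID2 (difference -4.93, adjusted p = 5.92e-08). H19 and Dlk1 had differences of -4.07 and -4.12 between AID-JARID2 and SUZ12-AID. Against MTF2-AID, AID-JARID2 had larger effects on Utf1 (4.88), Foxd3 (4.30), Foxf1 (-4.50) and Cdx4 (-4.76). Untreated Cdx4 was far lower in MTF2-AID than in AID-JARID2 and had almost no room to fall there. Its difference therefore does not show an unlike response to auxin. The test called 313 genes higher and 1427 lower for MTF2-AID minus SUZ12-AID, 1410 and 2355 for AID-JARID2 minus SUZ12-AID, and 1980 and 1833 for AID-JARID2 minus MTF2-AID. The split depended on scaling and on 1 library: quantile normalization gave 573 and 1049 in the first and 2098 and 2058 in the second. Without untreated SUZ12-AID replicate 1 these were 1072 and 1391, and 2194 and 2262. The third turned round with a pseudocount of 0.1 (1860 and 1873) and with a filter at 5 TPM (1645 and 1750). The 1740 calls of the first became 909 without SUZ12-AID auxin replicate 2, 1046 without untreated MTF2-AID replicate 1, and 1080 and 984 without MTF2-AID auxin replicates 1 and 2. The 3765 of the second became 2514 without AID-JARID2 auxin replicate 2.

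Among lists, the endothelial effect in MTF2-AID was below that in SUZ12-AID (median difference -1.81, camera adjusted p = 5.24e-14, adjusted p = 0.0693 with an estimated correlation). So was that of the cell-cycle inhibitors (median difference -1.03, camera adjusted p = 2.66e-07, adjusted p = 0.0478 with an estimated correlation). The cardiac progenitor effect in AID-JARID2 was below that in SUZ12-AID (median difference -2.28, camera adjusted p = 2.54e-16, adjusted p = 0.0538 with an estimated correlation). It was also below that in MTF2-AID (median difference -1.60, camera adjusted p = 4.28e-13, adjusted p = 0.0617 with an estimated correlation). The Hox effect in AID-JARID2 was below that in SUZ12-AID (median difference -1.17, camera adjusted p = 3.86e-07, adjusted p = 0.0538 with an estimated correlation). The trophoblast effect was below it too (median difference -2.14, camera adjusted p = 2.46e-09, adjusted p = 0.045 with an estimated correlation). For pluripotency genes the AID-JARID2 effect exceeded that in MTF2-AID (median difference 0.98, camera adjusted p = 1.19e-05, adjusted p = 0.186 with an estimated correlation).

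The overlap of calls asked whether the lines changed the same genes. SUZ12-AID and AID-JARID2 shared 999 increased genes, Sox2, Perp and Cd34 among them. If calls were independent 460.4 would be shared (two-sided Fisher exact test, odds ratio 4.01, adjusted p = 4.8e-172). They shared 296 decreased genes against 107.7 for independent calls (odds ratio 4.68, adjusted p = 6.12e-70), among them Hoxb1, Cdx2, Foxf1 and Hand1. Genes that rose in SUZ12-AID and fell in AID-JARID2, such as Hand2, numbered 306, below 400.7 for independent calls (adjusted p = 3.01e-08). The opposite way went 89, against 123.8 for independent calls (adjusted p = 8.22e-04). Genes are not independent replicates and both lines were tested with the same spread per gene, which can raise overlap. Fisher p values here therefore overstate the evidence. A shared spread would raise matching and opposite calls alike, whereas opposite calls lay below the counts for independent calls. Of the 7 increased genes of MTF2-AID 4 rose in SUZ12-AID (adjusted p = 0.0295), and 1 of the 3 decreased genes fell there (adjusted p = 0.176). Without SUZ12-AID auxin replicate 2 the shared genes numbered 555 and 140, and without untreated SUZ12-AID replicate 1 the shared decreases were 577. Shared decreases were 559 with median-of-ratios scaling, 568 with quantile normalization and 692 with voom on recovered reads. With a variance weight per line the shared genes numbered 561 and 130. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.301 between SUZ12-AID and AID-JARID2, -0.088 between SUZ12-AID and MTF2-AID, and -0.07 between MTF2-AID and AID-JARID2.

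The untreated groups of the lines were compared as the background of these effects. Mixl1 (chromosome 1, 180693043 to 180697034, minus strand), a homeobox gene of the primitive streak, stood at 8.71 ± 1.4 TPM in SUZ12-AID, 9.29 ± 0.167 TPM in MTF2-AID and 172 ± 6.77 TPM in AID-JARID2. The streak gene Eomes, the NODAL co-receptor gene Tdgf1, Fst and L1cam were higher in untreated AID-JARID2 than in SUZ12-AID by 3.83, 3.82, 3.41 and 3.26 on the log2 scale. Msgn1 and Cdx4 were higher than in MTF2-AID by 4.24 and 3.97. The claudin Cldn4 stood at 9.90 ± 0.481 TPM in AID-JARID2 against 183 ± 14.1 TPM and 127 ± 14.5 TPM in SUZ12-AID and MTF2-AID. Gpnmb stood at 0.658 ± 0.288 TPM against 23.2 ± 1.27 TPM and 19.4 ± 2.83 TPM. Hbb-bh1 was lower than in SUZ12-AID in both MTF2-AID (-2.65) and AID-JARID2 (-4.42). Nkx1-2, Cartpt and Hoxd3 were higher in MTF2-AID than in SUZ12-AID by 2.17, 2.04 and 1.80. Of the 10 genes that the rule took for this pair, 5 lost their call under at least 1 alternative, 3 of them not short RNAs. Between untreated MTF2-AID and SUZ12-AID 861 genes were higher and 494 lower, 768 and 724 with median-of-ratios scaling. For AID-JARID2 the numbers were 2382 and 1937 against SUZ12-AID and 2482 and 2751 against MTF2-AID. The excess of higher genes against SUZ12-AID turned round with median-of-ratios scaling (2008 and 2400), quantile normalization (2140 and 2399) and voom on recovered reads (2480 and 2708). It also did among changes of at least 2-fold (441 and 481) and without untreated SUZ12-AID replicate 1 (1626 and 1920), against 3923 and 1719 without replicate 2. The 2 other pairs turned round in 1 alternative each: MTF2-AID against SUZ12-AID with the libraries of the compared groups only (63 and 68), and AID-JARID2 against MTF2-AID with a filter at 5 TPM (2224 and 2170). The 1355 calls of the first pair became 803 and 4092 without untreated SUZ12-AID replicates 1 and 2, and 523 and 526 without untreated MTF2-AID replicates 1 and 2. The 4319 of the second became 2647 and 2352 without untreated AID-JARID2 replicates 1 and 2, and the 5233 of the third became 3399 without untreated AID-JARID2 replicate 2.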

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

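Of the tests in this part, those of a variance weight per line, of genes silent without auxin and of changes of at least 2-fold were chosen after the results were seen. The first replaced a planned test of a larger replicate spread in MTF2-AID, which the median replicate differences of 0.103 and 0.088, near those of AID-JARID2, had already answered.

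The results here drew attention because a test of the difference itself separated the effect of auxin between lines. For MTF2-AID minus SUZ12-AID it called 1740 genes. Hbb-bh1 (log2 difference 2.62) was among the largest positive differences and Cdkn2a (-3.95), Anxa1 (-3.65) and Sox18 (-3.45) among the negative ones. The short RNA genes Mir133a-2 (4.22), Mir7655 (3.96), Snora47 (3.29), Mir145a (2.604), AF357359 (-4.47) and Mir7036 (-4.30) rest on few reads. For AID-JARID2 minus SUZ12-AID it called 3765 genes, with Hbb-bh1 (3.75) and Eras (3.67) above 0, and Hand2 (-4.93), Dlk1 (-4.12) and H19 (-4.07) below. Its short RNA genes were Mir421 (4.41), Mir6941 (3.97), Scarna2 (3.72) and Mir483 (-4.51). For AID-JARID2 minus MTF2-AID it called 3813 genes, with Utf1 (4.88), Pde2a (4.80), Foxd3 (4.30) and Eras (4.28) above 0, Cdx4 (-4.76), Foxf1 (-4.50), Col1a1 (-4.30) and Pmp22 (-4.27) below, and Mir363 (6.68) and Mir133a-2 (-4.54) as short RNA genes. Untreated Hbb-bh1 stood at 34.4 ± 9.56 TPM in SUZ12-AID, 4.66 ± 1.59 TPM in MTF2-AID and 0.650 ± 0.419 TPM in AID-JARID2, so it had almost no room to fall in AID-JARID2 and less room in MTF2-AID. Its differences therefore do not show an unlike response to auxin. Nor does that of Cdx4 between AID-JARID2 and MTF2-AID, as untreated Cdx4 had almost no room to fall in MTF2-AID. Hbb-bh1 lost its call against SUZ12-AID with a pseudocount of 0.1 and on recovered reads in both differences, and for MTF2-AID also without SUZ12-AID auxin replicate 2, without untreated MTF2-AID replicate 2 and with a variance weight per line.

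Auxin changed 10 genes in MTF2-AID against 2997 and 5710 in the other lines. Low depth is argued against, since AID-JARID2 had 5386 calls when every library was thinned to the reads of the shallowest. The spread of the other lines in the pooled test explains part at most: a variance weight per line raised the count from 10 to 164, which was 13.7% of the SUZ12-AID count under the same weights. A swap between an untreated and an auxin library is argued against by the other divisions of the 4 MTF2-AID libraries, which called 1 and 5 genes. Whether auxin removed the MTF2 protein stays open, because the degron acts on the protein and the Mtf2 transcript changed by 0.19 on the log2 scale; a small role of MTF2 in these cells may also explain the count.

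Of the SUZ12-AID calls 78.8% were increases, which the loss of a repressor would give. Unequal depth is argued against, as thinning left the share at 78.6%. A release of silent genes covers a minority of all increased genes, since 16.9% of them were under 1 TPM without auxin. That share was not computed for increases of at least 2-fold, nor for all genes kept, so it does not show whether silent genes rose more often than others. The filter at 1 TPM in 2 libraries also left out genes that stayed below it with auxin, which can lower the share. Among changes of at least 2-fold, 664 were increases and 40 decreases (94.3%). For these, scaling and a single SUZ12-AID library are argued against as the cause, since the share stayed at 91.9% with median-of-ratios scaling, 78.8% with quantile normalization and at least 92.2% without any 1 SUZ12-AID library. Over all calls the excess of increases may come in part from 1 library: without untreated replicate 1 the share was 56.1%, the shares without 1 SUZ12-AID library ranged from 56.1% to 83.2%, and untreated SUZ12-AID had the largest replicate difference. Scaling stays open over all calls. The share was 61% with median-of-ratios scaling, past the bound of 60% set in advance, and 53.1% with quantile normalization. Both scalings pull the median log2 fold change of 0.06 to 0.00 and -0.04, so they lower the share by construction and that bound decided nothing. The direction of Cdkn2a, Nkx2-5 and Esx1 does not hang on this, as their calls held under each alternative.

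The average effect over the lines was set against other divisions of the libraries into treatments within lines. Of 100 splits drawn from 108 possible, the real one included, 2 called at least as many genes, under the bound set in advance. The real split called 4164 genes and the highest other 4464, and that other split exchanged the treatments of MTF2-AID while keeping the divisions of the other lines. Splits that kept the AID-JARID2 libraries divided as treated called 696 to 4464 genes and the other splits 0 to 4. The count of splits thus does not show that each line takes part in the average.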

How the results depend on the processing

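The alternatives on recovered reads, thinned reads, without short RNAs and with a variance weight per line were chosen after seeing the data. Of the counts recomputed under alternatives other than leaving out a library, 172 stayed within 1.5 times the value reported and 38 did not. Without 1 library 156 did and 24 did not. Among 9093 recomputed values of named genes, 365 lost and 30 gained a call. No named gene that passed in the planned fit or in the alternative changed direction between them. Changes of sign in genes that passed in neither were not counted. Without 1 library the calls ranged from 1322 to 3438 in SUZ12-AID, 3 to 40 in MTF2-AID and 3697 to 6654 in AID-JARID2, and from 3089 to 5044 for the average. They ranged from 909 to 2463, 2514 to 4456 and 2614 to 4721 for the differences MTF2-AID minus SUZ12-AID, AID-JARID2 minus SUZ12-AID and AID-JARID2 minus MTF2-AID, and from 523 to 4092, 2352 to 5642 and 3399 to 6125 for the same pairs untreated. Shared increases ranged from 555 to 1161 and shared decreases from 140 to 577, and lists called from 11 to 15, 7 to 11 and 14 to 15 in SUZ12-AID, MTF2-AID and AID-JARID2. A group left with 1 library was assumed to vary like the others. MTF2-AID had 6 calls with a pseudocount of 0.1, 30 with 5, 21 without a filter, 17 with quantile normalization and 18 without short RNAs. Shared decreases were 559 with median-of-ratios scaling, 568 with quantile normalization and 692 with voom on recovered reads. With the libraries of the compared groups only, calls were 1144 in SUZ12-AID, 5 in MTF2-AID, 1082 for MTF2-AID minus SUZ12-AID, and 131 and 2232 for untreated MTF2-AID and AID-JARID2 against SUZ12-AID, with fewer libraries behind each spread. With the replicate number as a block MTF2-AID had 4 calls and untreated MTF2-AID against SUZ12-AID 2156, though the numbers do not pair the libraries (correlations 0.096, -0.039 and 0.008). At an absolute log2 fold change of at least 1, a stricter rule by construction, 704, 5 and 1525 genes were left in SUZ12-AID, MTF2-AID and AID-JARID2, 222 for the average, 876, 1466 and 1702 for the differences, 142, 922 and 1199 for the untreated pairs, and 189 and 15 for the overlaps. With a variance weight per line, which gives SUZ12-AID its own larger spread, calls were 1194 in SUZ12-AID, 164 in MTF2-AID, 1103 for MTF2-AID minus SUZ12-AID and 845 for the same pair untreated, and the overlaps 561 and 130. Lists called were 0, 0 and 0 with an estimated correlation, and 24 in SUZ12-AID and 6 in MTF2-AID with fry. Where no reason is given the cause was not tested. Depth limits the short RNA genes, whose calls rest on a few reads.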

Other observations

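In this part the tests of shared untreated libraries and of a partial loss of JARID2 activity, and the Y-linked genes, were chosen after the results were seen. In several gene lists most members in untreated AID-JARID2 cells lay on the same side of the mean of the other untreated lines. These are given here without a test. Primitive streak and early mesoderm genes had a median log2 difference of 1.46, with 19 of 21 members higher, and secreted signalling factors 0.51, with 24 of 33 higher. Endothelial genes had a median of -1.29 (3 of 21 higher), blood genes -0.99 (2 of 17), germline genes -0.89 (0 of 15), p53 targets -0.73 (2 of 19), Hox genes -0.66 (6 of 24) and cell-cycle inhibitors -0.59 (4 of 13). Proliferation genes had a median of 0.19, with 20 of 22 higher. Stress genes had a median of -0.38, with 2 of 20 higher.

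Transcripts of the Y chromosome differed between the lines. Ddx3y (chromosome Y, 1260771 to 1286629, minus strand) stood at 7.45 ± 0.760 TPM in untreated and 10.7 ± 1.37 TPM in auxin SUZ12-AID, was listed at 0 in all 4 MTF2-AID libraries, and stood at 0.169 ± 0.0136 TPM and 0.296 ± 0.151 TPM in AID-JARID2. Eif2s3y had 11.5 ± 0.604 TPM and 15.8 ± 0.800 TPM in SUZ12-AID, 0 in MTF2-AID, and 0.170 ± 0.0137 TPM and 0.450 ± 0.0808 TPM in AID-JARID2. Kdm5d and Uty were 3.30 ± 0.836 and 2.63 ± 0.832 TPM in untreated SUZ12-AID and listed at 0 in MTF2-AID. Xist had a mean of 0.0108 to 0.245 TPM over the 6 groups.

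A further idea was that untreated AID-JARID2 cells already lean towards the auxin effect of their line. The untreated difference and the auxin effect, each with its own untreated library, had a Pearson r of -0.011 and -0.009 across genes, so the pattern itself was not seen. With both untreated libraries in each difference r was -0.081, but a shared library enters with opposite signs and lowers r by construction, so this value tests nothing. A partial loss of JARID2 activity before auxin stays open. Its criterion, written after related values were seen, was a correlation at least 0.1 higher with the AID-JARID2 than with the SUZ12-AID effect, and the differences of 0.133 and 0.142 met it, but the correlations were -0.038 against -0.172 and -0.18, so neither effect resembled the untreated difference. The criterion was therefore set aside after the values were seen. Slower differentiation of the line also stays open. The pluripotency median of 0.14 and the cardiac progenitor median of -0.01 met the criterion set in advance. However, 14 of 26 and 12 of 24 members were higher, so members of these lists went both ways. Outside the criterion, primitive streak genes had a median of 1.46 (19 of 21 higher) and contractile genes of -0.32 (5 of 22 higher). Whether slower differentiation gave these was not tested.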
